A study of Mus musculus with 12 samples.

How the data were processed

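Deposited MAS5 signal of 12 Affymetrix arrays from sorted mouse prostate epithelium was analysed. Per the labels' protocols, RNA of sorted cells was isolated with the RNeasy Micro kit, amplified with the NuGEN Pico kit, and biotin-labelled for hybridization. The signal intensity deposited by the authors was computed with MAS5, per the submitters' processing notes; its version was not given in the sources used here. Values were on the linear scale, without missing entries, and the mean of each array after trimming 2% from each end lay at 499.8, so arrays had already been scaled to 1 target. Array medians were 57.7 to 99.95. Ratios of 3' to 5' control probe sets were 4.18 to 8.70 for Gapdh and 0.781 to 1.11 for Actb. Detection calls were not used here.

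The table held 45101 probe sets, 64 of them controls, which were left out. A given annotation table assigned 1 gene symbol to 34945, several to 932 and none here to 9160. Entrez identifiers of 34741 of the 1-symbol probe sets matched the supplied mouse gene table (GRCm38.p6 annotation), and no symbol needed updating. Values were transformed as log2 of signal plus 16. Probe sets above the 40th percentile of their array on at least 3 arrays were kept, and the probe set with the highest mean over all arrays stood for each gene, which left 14645 genes of 18193. Of 12 genes fixed to be reported, 9 were measured and the others were not analysed here.

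The 4 group means were fitted together with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, 8 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The contrasts were castrated against intact in luminal and in basal cells, luminal against basal in intact and in castrated mice, and the interaction. Of 28 gene lists, 26 had at least 5 measured members; the erythroid and the neuroendocrine and nerve lists had fewer and were not tested. The others covered androgen-dependent, luminal, basal, proximal luminal, progenitor, cell cycle, antigen presentation, interferon, inflammatory, immediate early, endoplasmic reticulum, polyamine, cholesterol and fatty acid, oxidative phosphorylation, glutathione, apoptosis, Notch, Wnt, TGF-beta and BMP, steroid, fibroblast, smooth muscle, leukocyte, endothelial, seminal vesicle and reference genes. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over all 130 tests, and again with an estimated correlation. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

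Groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. Genes were named as the 5 largest rises and 5 largest falls per comparison among those passing with non-overlapping groups (for the interaction, those passing), up to 4 members per list with the lowest adjusted p, the fixed genes in every comparison, and the 5 shared genes per direction with the largest smaller change. Genes known only by provisional identifiers were skipped. Herc3, Steap4, Dcn, Fbln1 and Tyrobp in basal cells and members of later lists were named outside that rule. So were the fatty acid enzymes and Mvd in basal cells.

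The design text speaks of 3 replicate sets with paired intact animals, and the pairing was taken from the replicate numbers. After removal of group means, arrays of equal number correlated across genes between -0.00723 and 0.0258. As chosen before the data were examined, the replicate number was left out of the principal model and used as a block in an alternative. Treating the luminal and the basal array of equal number, both intact or both castrated, as a random block gave a consensus correlation of 0.0125. Further alternatives were quantile normalization, median centring, other added constants (1 and 64), no or a stricter filter, 2-group fits, no intensity trend, other probe set handling, array weights, a self-contained list test and leaving out each array. Leaving out both arrays of lowest weight and 3 further lists (second fibroblast, squamous, hypoxia) were chosen after seeing the data. For carried luminal RNA, an earlier test on the 6 cholesterol genes that fell in basal cells (median luminal minus basal difference -1.43 in intact mice) was replaced by a test on all 21 members (median -0.0136), since those 6 had been picked on the same intact basal arrays. The pipeline was tested on simulated data: in 20 simulations with 200 changed genes, 3.4% of 2-fold and 23.7% of 4-fold changes were recovered, 4.24% of calls were false, and a shifted list was called in all 20. Without a shifted list, 4 list calls were made over all simulations. Noise was drawn independently for each gene, with the same spread in every group. The simulations therefore do not show how calls hold up with correlated genes or unequal spread. With 200 genes changed, their recovered shares do not carry over to comparisons with more changed genes. Probe sets with several or no symbols were left out of gene-level tests and counted apart.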

Results

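Gene expression was measured in epithelial cells of the mouse prostate on 12 Affymetrix arrays. C57BL/6 males were castrated at 8 weeks of age or left intact, and tissue was taken 4 weeks after surgery. Dissociated cells negative for lineage markers and positive for the epithelial surface protein EpCAM were sorted by the integrin CD49f, low on luminal cells and high on basal cells. Luminal cells line the glandular lumen and secrete the prostatic fluid, and basal cells lie beneath them. The 4 groups (intact luminal, castrated luminal, intact basal and castrated basal) had 3 arrays each, 1 per biological replicate. Log2 signals of arrays of 1 group correlated with Pearson coefficients across genes from 0.863 to 0.967, genes not being independent replicates. Castrated luminal arrays were the most alike, with a median standard deviation of 0.32 log2 units per gene against 0.58 to 0.61 in the other groups. The first principal component, 36.5% of the variance, parted luminal from basal arrays, and the second, 16.01%, parted intact from castrated arrays. Intact luminal replicate 3 stood apart on the second component, at -93.7 against -29.8 and -32.4 for the other intact luminal arrays. Castrated basal replicate 3 stood apart on the third, at 82.2 against 5.52 and 7.95. So did intact luminal replicate 3 (67.8 against -4.45 and -2.79) and, the other way, intact basal replicate 3 (-56.6 against -22.1 and -28.5). In each of the 4 groups replicate 3 had the lowest array weight: 0.363 in intact luminal, 1.81 in castrated luminal, 0.504 in intact basal and 0.434 in castrated basal. All arrays of replicate 3 were not left out together, so a difference of that set was not tested. The number of arrays limits the precision of every value below. Fold changes are log2 ± standard error from limma, with n = 3 arrays per group, and adjusted p-values are over the 14645 genes tested. The standard error pools the spread of all 4 groups, so it is not that of the compared arrays alone. Castrated luminal arrays, the most alike, thus lower it in comparisons that do not include them.

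The first question was how luminal cells of castrated mice differed from those of intact mice. Each array measured a pool of sorted cells. Here and below, changes within cells and changes in which cells were sorted cannot be told apart. Secretory products fell most. The prostatic microseminoprotein gene Msmb fell by 8.56 on the log2 scale (-8.56 ± 0.93, adjusted p = 3.13e-05), and the seminal vesicle secretory protein genes Svs5 (-7.22 ± 0.52) and Svs6 (-7.41 ± 0.89) and the prostate transglutaminase Tgm4 (-7.21 ± 0.43) fell with it. Pbsn, which encodes the androgen-dependent secreted protein probasin, went from a mean signal of 61442 to 5160 (-3.57 ± 0.44, adjusted p = 1.13e-04). Pate14 (-7.93 ± 0.64) and the protease inhibitor Spink1 (-7.72 ± 2.12, adjusted p = 0.0396) completed the largest falls, Spink1 losing its call under 7 of the 12 leave-outs of 1 array. The largest rises were Ifit1bl1 (6.52 ± 1.11), the neutrophil-attracting chemokine Cxcl5 (5.76 ± 0.58), Ccdc3 (5.41 ± 0.38), the stress keratin Krt6a (5.24 ± 0.88) and Olfm4 (5.17 ± 0.57). Krt6a had signals of 436, 531 and 3.86 on the intact luminal arrays, and its change was 3.69 without the last of them. In all, 858 genes changed, 424 higher and 434 lower in castrated luminal cells, and 738 of them by at least 2-fold.

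In the androgen-dependent and androgen receptor-regulated list, of 21 measured members, 3 rose, 9 fell and 9 did not pass. Camera gave an adjusted p of 6.66e-04 and adjusted p = 0.0310 with an estimated correlation. The 3 members that rose were Ndrg1 (1.64 ± 0.19) and, chosen after their values were seen, Herc3 (2.52 ± 0.67) and Steap4 (2.25 ± 0.28). All 8 measured seminal vesicle secretory genes fell, with a median log2 fold change of -4.65. Whether seminal vesicle tissue contributed to the intact arrays was not tested. The list had an adjusted p of 3.95e-14 and adjusted p = 0.0255 with an estimated correlation. The protein-folding machinery of the endoplasmic reticulum fell as a group: of 25 measured members, 0 rose, 13 fell and 12 did not pass. Adjusted over the list alone, 0 rose and 18 fell. For the list, adjusted p = 2.09e-14, and adjusted p = 0.0310 with an estimated correlation. Its leading members were the chaperones Hsp90b1 (-1.16 ± 0.15), Hspa5 (-1.31 ± 0.19) and Calr (-0.91 ± 0.14), and the translocon-associated Ssr3 (-0.98 ± 0.16). Under median centring Calr and Ssr3 lost their calls. In the glutathione and oxidative stress list, of 21 measured members, 2 rose, 6 fell and 13 did not pass. The list test gave adjusted p = 0.00371, and adjusted p = 0.0924 with an estimated correlation. The glutathione transferase genes Gstm1 (-0.87 ± 0.16), Gstm2 (-1.11 ± 0.24) and Gsta3 (-2.07 ± 0.43) and the extracellular glutathione peroxidase Gpx3 (-3.29 ± 0.73) were among those that fell, Gstm1 and Gstm2 losing their calls under median centring.

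Inflammatory and NF-kB genes shifted upward: of 21 measured members, 4 rose, 2 fell and 15 did not pass. Adjusted over the list alone, 10 rose and 2 fell. Tested together, they had an adjusted p of 4.40e-04 and adjusted p = 0.0310 with an estimated correlation. Cxcl2 (3.35 ± 0.50), Cxcl1 (1.37 ± 0.21) and the adhesion molecule Icam1 (1.43 ± 0.26) rose beside Cxcl5. Class II antigen presentation genes H2-Aa (4.28 ± 0.81) and H2-Eb1 (2.92 ± 0.73) rose, whereas the class I light chain B2m fell (-1.13 ± 0.13). Over the whole antigen presentation list, of 16 measured members, 2 rose, 1 fell and 13 did not pass. By camera, adjusted p = 0.00371 for the list, and adjusted p = 0.122 with an estimated correlation. H2-Eb1 lost its call under 5 of the 12 leave-outs. The leukocyte marker list did not rise beside them: its median log2 fold change was -0.67 and 0 of its 14 members rose (adjusted p = 0.185, or adjusted p = 0.295 with an estimated correlation). The interferon list passed camera upward, although none of its 17 members passed alone, Ifit3 coming closest (2.80 ± 0.87, adjusted p = 0.0721). Tested together, they had an adjusted p of 0.0429 and adjusted p = 0.131 with an estimated correlation. That list had an adjusted p of 0.0727 with quantile normalization, 0.0840 with median centring, 0.0584 with 1 added in place of 16, 0.0924 with a stricter filter, 0.0880 with the mean of a gene's probe sets, 0.0514 and 0.0751 without castrated luminal replicate 2 and 3, and 0.0599, 0.0593 and 0.0613 without intact luminal replicate 1, 2 and 3.

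Of 16 luminal identity genes 1 rose and 1 fell, and of 21 basal identity genes 2 rose and 1 fell. Over all genes tested 5.86% changed. The basal identity list did not pass camera (adjusted p = 0.898). Genes that did not pass may still have changed, since the simulations, with 200 changed genes, recovered 3.4% of 2-fold changes. With 858 genes called here the adjusted cutoff was less strict, so that share is not the recovery in these data. Krt8 (0.12 ± 0.17, adjusted p = 0.751) and Krt18 (-0.36 ± 0.16, adjusted p = 0.210), the keratins of luminal cells, did not pass, although with quantile normalization Krt8 passed at 0.68 and Krt18 turned to 0.41 and passed. Of 16 luminal identity genes, Cdh1 rose (0.87 ± 0.18) and Cd24a fell (-0.51 ± 0.13, turning to 0.02 with quantile normalization); the list did not pass. As a list they had an adjusted p of 0.964 and adjusted p = 0.976 with an estimated correlation. Among basal identity genes, already low in luminal cells, Trp63 fell (-1.92 ± 0.43) while Krt17 (1.89 ± 0.42) and the water channel Aqp3 (3.44 ± 0.56) rose. Krt5 (-1.77 ± 0.68, adjusted p = 0.150), Krt14 (-0.63 ± 0.48, adjusted p = 0.524), Psca (-2.09 ± 1.16, adjusted p = 0.347), Krt4 (0.62 ± 0.67, adjusted p = 0.672) and the proliferation marker Mki67 (-2.01 ± 0.78, adjusted p = 0.157) did not pass. The retinaldehyde dehydrogenase Aldh1a3 (4.86 ± 0.67) and Ly6d (2.51 ± 0.63) rose out of the 13 genes of the castration-resistant or proximal luminal list, which did not pass. Camera gave an adjusted p of 0.434 and adjusted p = 0.627 with an estimated correlation. The progenitor-associated genes Cd44 (2.82 ± 0.33) and Runx1 (1.83 ± 0.29) rose while Id3 (-1.97 ± 0.25) and Aldh1a1 (-2.23 ± 0.30) fell.

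Of 17 apoptosis regulators, 3 rose, 1 fell and 13 did not pass. The pro-apoptotic Bcl2l11 (1.70 ± 0.27) and Bid (2.64 ± 0.63) and the anti-apoptotic Birc3 (1.21 ± 0.31) rose, and the anti-apoptotic Bcl2 fell (-1.48 ± 0.26). The list had an adjusted p of 0.0676 and adjusted p = 0.160 with an estimated correlation. TGF-beta and BMP genes passed upward, with Smad2 (1.39 ± 0.35) and Smad3 (2.83-fold) higher and Bmp4 lower (-2.36 ± 0.59). By camera, adjusted p = 0.0127 for the list, and adjusted p = 0.0924 with an estimated correlation. Cholesterol and fatty acid synthesis genes passed upward, 3 of 21 having risen: Cyp51 (1.30 ± 0.32), Sqle (1.57 ± 0.40) and Hmgcs1 (0.90 ± 0.24). As a list they had an adjusted p of 0.0424 and adjusted p = 0.384 with an estimated correlation. The call was lost with quantile normalization (0.123), the self-contained test (0.227), a stricter filter (0.0924) and the mean of a gene's probe sets (0.0839). Without intact luminal replicate 3 that list had an adjusted p of 0.300, without castrated luminal replicate 3 of 0.0912 and without intact basal replicate 3 of 0.0513. Cyp51, Hmgcs1, Smad2, Smad3 and Bid each lost their calls under 4 of the 12 leave-outs, as did Ly6d and Jun, and Sqle under 5. Immediate early genes, which dissociation can induce, passed downward: of 18 measured members, 1 rose, 5 fell and 12 did not pass (adjusted p = 9.83e-04, or adjusted p = 0.368 with an estimated correlation), among them Jund (-0.88 ± 0.15) and Jun (-0.82 ± 0.20). Under median centring the median of all genes moved from -0.09 to 0.29, and Jund, Jun and the list (adjusted p = 0.149) lost their calls. The list had an adjusted p of 0.0590 with quantile normalization, 0.0872 with the self-contained test and 0.0590 without intact luminal replicate 3.

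Markers of other cell types moved with castration in luminal arrays. Of 12 measured fibroblast genes, 0 rose, 8 fell and 4 did not pass, with a median log2 fold change of -3.03. For the list, adjusted p = 1.28e-13, and adjusted p = 0.0145 with an estimated correlation. Sparc went from a mean signal of 2415 to 19.1 (-5.90 ± 0.54), and Dcn (-2.76 ± 0.25), Mgp (-3.30 ± 0.43) and Col1a2 (-4.40 ± 0.60) fell too. The smooth muscle (adjusted p = 0.0138, or adjusted p = 0.274 with an estimated correlation) and endothelial lists (adjusted p = 0.0349, or adjusted p = 0.131 with an estimated correlation) passed downward with no member passing alone, and had adjusted p-values of 0.151 and 0.149 without intact luminal replicate 3; the endothelial list also lost its call without castrated luminal replicate 3 (0.0663) and intact luminal replicate 1 (0.0521), with quantile normalization (0.0747), with 64 added (0.0590) and with a stricter filter (0.0739). The erythroid gene Hbb-b2 fell (-3.76 ± 0.57). Of the 73 named genes that changed, 12 lay under the 40th percentile of the array on all 3 arrays of the dimmer group, including Cxcl5, Ccdc3, Pate14, Svs6 and Sparc, so that the size of their fold depends on the constant added before the logarithm.

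The count rested on the castrated luminal arrays, on the model and on scaling. It was 555 without an intensity trend, 1945 with array weights and 1562 with every probe set tested singly. It was 444, 433 and 401 without castrated luminal replicate 1, 2 and 3, and 564 without intact luminal replicate 3; under median centring 1021 genes were higher and 252 lower.

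**Figure D1:**
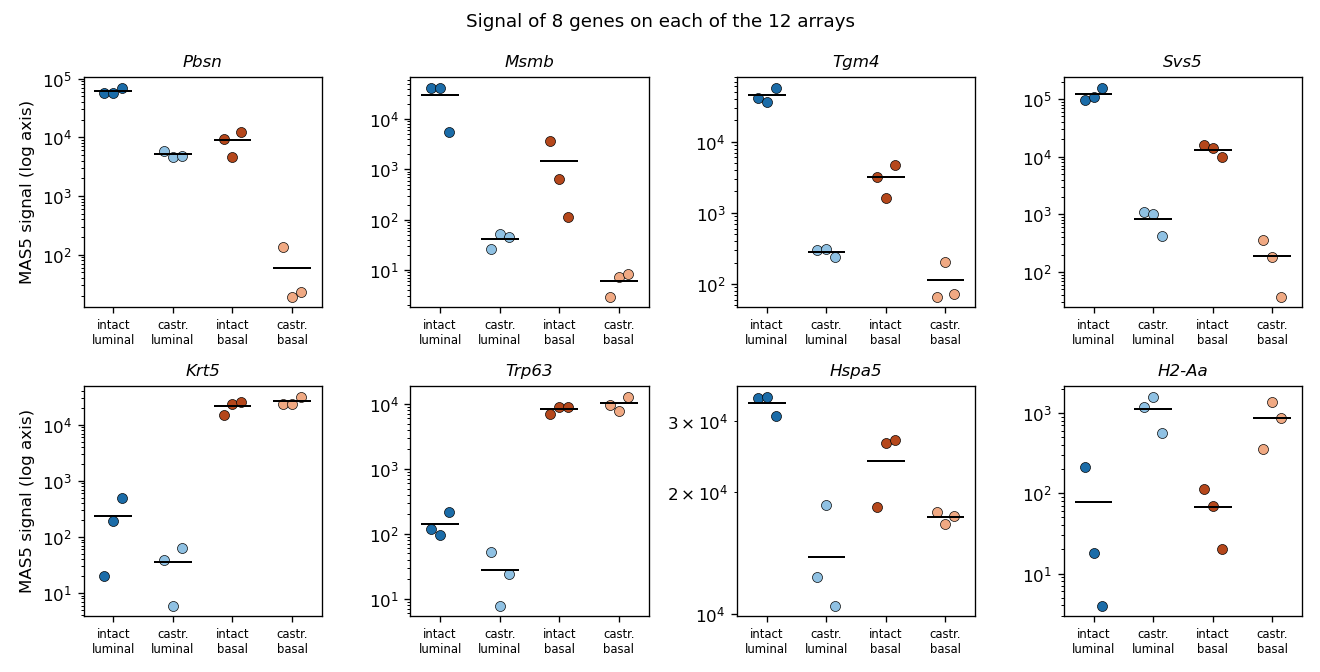
MAS5 signal on a logarithmic axis for 8 genes in each of the 4 groups, with 1 point per array (3 per group) and a line at the group mean. Pbsn, Msmb, Tgm4 and Svs5 lie lower in castrated arrays of both cell types, and Krt5 and Trp63 separate basal from luminal arrays with and without castration.

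The second question was whether basal cells, which survive castration in large part, respond too. Secretory genes led the falls here as well: Svs2 (-7.53 ± 0.57, adjusted p = 1.07e-06), Pbsn (-7.12 ± 0.44), Svs4 (-7.06 ± 0.64), Fcgbp (-6.74 ± 0.62) and Svs5 (-6.36 ± 0.52). Pbsn had a mean signal of 8864 in intact and 58.7 in castrated basal arrays. The largest rises were Nradd (4.26 ± 0.73), the actin regulator Pfn2 (3.82 ± 0.41), the lysosomal protease Ctss, which myeloid cells express too (3.45 ± 0.53), H2-Aa (3.38 ± 0.81) and the activin antagonist Fst (3.35 ± 0.61). Of the 49 named genes that changed, 4 were dim on all 3 arrays of the dimmer group (Svs4, Msmb, Gsdmc2 and Hbb-b2). In all, 384 genes changed, 164 higher and 220 lower, 342 of them by at least 2-fold.

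In the androgen-dependent list, of 21 measured members, 0 rose, 4 fell and 17 did not pass. Pbsn, Tgm4 (-4.65 ± 0.43), Msmb (-4.94 ± 0.93) and the transcription factor Zbtb16 (-2.12 ± 0.38) fell. The list test gave adjusted p = 1.02e-04, and adjusted p = 0.0244 with an estimated correlation. Seminal vesicle genes passed downward with 3 of 8 fallen. Tested together, they had an adjusted p of 7.05e-05 and adjusted p = 0.122 with an estimated correlation. The cholesterol and fatty acid synthesis list passed downward: of 21 measured members, 0 rose, 6 fell and 15 did not pass. Adjusted over the list alone, 0 rose and 10 fell. By camera, adjusted p = 1.07e-06 for the list, and adjusted p = 0.0816 with an estimated correlation. Insig1, a sterol-responsive regulator (-2.46 ± 0.33, adjusted p = 7.18e-04), Hmgcs1 (-1.53 ± 0.24), Cyp51 (-1.71 ± 0.32) and Idi1 (-2.08 ± 0.39), enzymes of the mevalonate and sterol pathway, led them. The fatty acid enzymes of the list did not pass: Fasn (-0.35), Acaca (-0.34), Acly (-0.32), Scd1 (-0.52), Scd2 (-0.87), Elovl6 (-0.54) and Elovl5 (0.70). Some sterol enzymes, such as Mvd (-0.46), did not pass either. The castration-resistant or proximal luminal list passed upward: of 13 measured members, 4 rose, 0 fell and 9 did not pass. As a list they had an adjusted p of 3.57e-06 and adjusted p = 0.0486 with an estimated correlation. Those that rose were Clu (1.92 ± 0.23), Krt4 (2.91 ± 0.67), Gsdmc2 (3.60 ± 0.89) and Cyp2f2 (1.59 ± 0.41); Gsdmc2 and Cyp2f2 each lost their call under 10 of the 12 leave-outs, and Krt4 under 5. The luminal identity list passed upward too (adjusted p = 0.0209, or adjusted p = 0.160 with an estimated correlation), with Krt19 (1.19 ± 0.18) and Epcam (0.73 ± 0.14) higher and the homeobox gene Hoxb13 lower (-2.91 ± 0.48); the list had an adjusted p of 0.0678 without castrated basal replicate 3 and 0.107 without intact basal replicate 2, and 0.206 with the self-contained test.

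Basal keratins and p63 did not pass: the p63 gene Trp63 (0.26 ± 0.43, adjusted p = 0.805), Krt5 (0.31 ± 0.68, adjusted p = 0.862) and Krt14 (0.26 ± 0.48, adjusted p = 0.833), and of 21 members Aqp3 alone rose (2.55 ± 0.56). Krt8 (0.34 ± 0.17, adjusted p = 0.295), Psca (0.65 ± 1.16, adjusted p = 0.824) and Mki67 (-0.83 ± 0.78, adjusted p = 0.637) did not pass either; Krt18 (0.39 ± 0.16, adjusted p = 0.198) passed with quantile normalization or median centring. H2-Eb1 rose (2.95 ± 0.73) beside H2-Aa, while the antigen presentation list did not pass (adjusted p = 0.0534, or adjusted p = 0.274 with an estimated correlation); H2-Aa and H2-Eb1 lost their calls under 7 and 10 of the 12 leave-outs. The macrophage gene Lyz2 rose beside them (2.40 ± 0.59, adjusted p = 0.0398; 0.0589 with the replicate number as a block), from a mean signal of 105 to 566, and the myeloid gene Tyrobp went from 72.9 to 482 without passing (2.70 ± 0.82, adjusted p = 0.0873). Members of the leukocyte list went both ways, with a median log2 fold change of -0.03; adjusted over the list alone, 2 rose and 1 fell. Camera gave an adjusted p of 0.434 and adjusted p = 0.507 with an estimated correlation. The chemokine Ccl2 fell (-3.52 ± 0.73), and the inflammatory list did not pass. The list had an adjusted p of 0.385 and adjusted p = 0.444 with an estimated correlation. The endoplasmic reticulum list passed downward, with Hsp90b1 (-0.92 ± 0.15) and Dnajc3 (-0.96 ± 0.23) lower and Herpud1 higher (1.25 ± 0.24), with adjusted p = 0.0128, or adjusted p = 0.338 with an estimated correlation. Its adjusted p was 0.302 under median centring, 0.0656 with the self-contained test and 0.138 with the mean of a gene's probe sets, and without castrated basal replicate 2, intact basal replicate 2 and intact basal replicate 3 it was 0.0662, 0.0890 and 0.0645. Fibroblast genes fell: of 12 measured members, 0 rose, 6 fell and 6 did not pass (adjusted p = 2.72e-09, or adjusted p = 0.0222 with an estimated correlation), among them Col1a2 (-4.39 ± 0.60), Sparc (-3.93 ± 0.54) and Dpt (-3.96 ± 0.75), whereas Dcn, at mean signals of 21080 and 22092, did not pass (0.06 ± 0.25, adjusted p = 0.931). Gpx3 (-4.07 ± 0.73) and Hbb-b2 (-4.27 ± 0.57) fell as in luminal arrays. Lyz2, Dnajc3, Aqp3 and Ccl2 lost their calls under 9, 8, 4 and 3 of the leave-outs, and Hsp90b1 and Dnajc3 under median centring.

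The basal count moved with the model, with single arrays and with scaling. It was 120 in a fit over the 2 basal groups, which takes no spread from luminal arrays. The count was 155 without an intensity trend, 202 with array weights and 618 with every probe set tested singly. It was 175 and 220 without castrated basal replicate 2 and 3, 227 and 194 without intact basal replicate 2 and 3, 184, 212 and 219 without castrated luminal replicate 1, 2 and 3, and 623 without intact luminal replicate 3; median centring gave 511 higher and 115 lower.

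**Figure D2:**
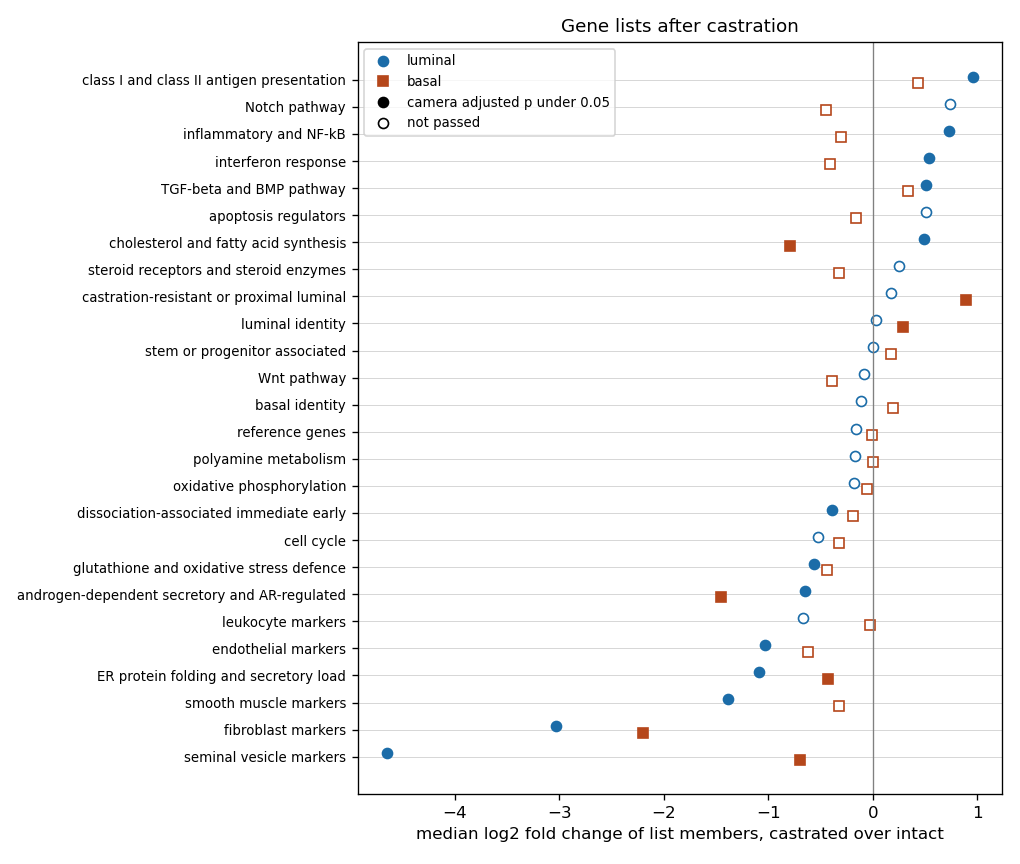
Median log2 fold change, castrated over intact, of the measured members of each of 26 gene lists in luminal (circles) and basal (squares) arrays, filled where camera's adjusted p was under 0.05. The seminal vesicle and fibroblast lists lie lowest in luminal arrays, at -4.65 and -3.03, and the cholesterol list lies at 0.49 in luminal and -0.79 in basal arrays.

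The responses of both cell types, which share no array, were set side by side. Of the genes called in both, 31 rose in both, 68 fell in both and 18 went opposite ways, where independent lists would share 4.75 rises and 6.52 falls. No such figure was computed for opposite changes. Both comparisons use the same variance estimate of each gene, and luminal and basal cells of equal replicate number may come from the same mice. Their calls are therefore not independent, and the excess does not measure a shared response. The shared rises with the largest smaller change were H2-Aa, H2-Eb1, the hydroxycarboxylic acid receptor Hcar2 (3.39 ± 0.59 in luminal and 2.60 ± 0.59 in basal arrays), Aqp3 and the cornified envelope gene Ivl (2.69 ± 0.55 and 2.35 ± 0.55). Hcar2 and Ivl each lost their basal calls under 5 of the 12 leave-outs. The shared falls were led by Fcgbp (-6.74 ± 0.62 and -6.74 ± 0.62), Svs5, Msmb, Svs4 and Tgm4. Across the 14645 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.293 and Spearman's rho = 0.260. The shared count was 41 without an intensity trend, 57 without castrated basal replicate 2, 44, 47 and 55 without castrated luminal replicate 1, 2 and 3, and 64 without intact basal replicate 2; median centring turned the split to 137 rises and 40 falls.

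Whether castration acted differently on the cell types was tested as an interaction, in which a positive value means a larger rise, or a smaller fall, in luminal cells. The difference passed for 168 genes, 99 positive and 69 negative. Tnfaip2 (6.32 ± 0.85), the G-protein regulator Rgs4 (5.94 ± 0.92), Mtmr11 (5.41 ± 1.06), the serine protease Htra1 (4.998 ± 0.81) and Casp12 (4.94 ± 0.80) were the largest positive values. Svs6 (-6.87 ± 1.26), Svs3a (-5.52 ± 0.95), the neurofilament gene Nefh (-5.49 ± 0.80), the complement gene C1s1 (-5.40 ± 0.86) and the defensin gene Defb42 (-5.26 ± 1.24) were the largest negative ones, Defb42 losing its call under 11 of the 12 leave-outs. Of these 10 genes, 6 lay under the 40th percentile on all 3 arrays of at least 1 group. Nefh did so in both basal groups, at mean signals of 5.42 and 2.40, so no basal change could be measured and its interaction value rests on its luminal change. From intact basal signal down to the constant added, the largest basal fall that could be measured was -1.38 for Svs6, -0.93 for Svs3a, -3.82 for C1s1 and -2.34 for Defb42. Luminal falls of all 5 negative genes were larger (-7.41, -4.62, -7.05, -6.60 and, for Nefh, -5.71). Pbsn fell less in luminal than in basal arrays (3.55 ± 0.62, adjusted p = 0.00906), and Tgm4 fell more (-2.56 ± 0.60, adjusted p = 0.0495; 0.0762 with the replicate block), Tgm4 losing its call under 9 of the leave-outs. Of the other fixed genes, Krt8 (-0.22 ± 0.24, adjusted p = 0.760), Krt18 (-0.75 ± 0.22, 0.129), Krt5 (-2.08 ± 0.96, 0.378), Krt14 (-0.89 ± 0.68, 0.643), Trp63 (-2.19 ± 0.61, 0.104), Psca (-2.73 ± 1.64, 0.520), Krt4 (-2.29 ± 0.94, 0.311) and Mki67 (-1.18 ± 1.10, 0.718) did not pass.

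With the preset correlation, cholesterol and fatty acid synthesis had the lowest p of the lists in the interaction; with an estimated one, and by the self-contained test, the inflammatory list lay lower. In the interaction, of 21 measured members, 5 were positive, 0 negative and 16 did not pass. Adjusted over the list alone, 9 were positive and 0 negative. For the list, adjusted p = 4.10e-08, and adjusted p = 0.0600 with an estimated correlation. Hmgcs1 (2.43 ± 0.34, adjusted p = 0.00269), Cyp51 (3.01 ± 0.46), Insig1 (2.79 ± 0.47) and the squalene epoxidase Sqle (3.33 ± 0.57) led them. Hmgcs1 had mean signals of 3517 in intact and 6647 in castrated luminal arrays, against 14899 and 5044 in basal arrays. Inflammatory genes were the 1 list whose interaction also passed with an estimated correlation (1 positive and 0 negative of 21, adjusted p = 1.93e-05, or adjusted p = 0.0222 with an estimated correlation); Cxcl5 passed (4.37 ± 0.83). Adjusted over the list alone, 7 were positive and 0 negative. The interferon (0 positive and 0 negative of 17, adjusted p = 0.00534, or adjusted p = 0.0600 with an estimated correlation) and apoptosis lists (1 positive and 1 negative of 17, adjusted p = 0.0278, or adjusted p = 0.106 with an estimated correlation) were positive as well. Bcl2l11 was positive (1.87 ± 0.38) and Bcl2 negative (-1.74 ± 0.36), losing their calls under 3 and 6 of the 12 leave-outs. The endoplasmic reticulum list was negative (0 positive and 3 negative of 25, adjusted p = 1.95e-06, or adjusted p = 0.106 with an estimated correlation), with Herpud1 (-2.48 ± 0.34), Ssr3 (-1.16 ± 0.23) and Ddit3 (-2.40 ± 0.47). The castration-resistant or proximal luminal (0 positive and 1 negative of 13, adjusted p = 0.00534, or adjusted p = 0.160 with an estimated correlation), fibroblast (0 positive and 1 negative of 12, adjusted p = 0.0339, or adjusted p = 0.238 with an estimated correlation) and seminal vesicle lists (1 positive and 3 negative of 8, adjusted p = 0.00915, or adjusted p = 0.274 with an estimated correlation) were negative, led by Clu (-2.10 ± 0.32; the call was lost with quantile normalization), Dcn (-2.82 ± 0.35) and Svs6. Quantile normalization gave adjusted p-values of 0.0610, 0.0626 and 0.0734 for these 3 lists, and the self-contained test 0.142, 0.0865 and 0.0632. The fibroblast list had 0.177 with 64 added and 0.241 with the mean of a gene's probe sets, which gave 0.0903 for the apoptosis list. The proximal list had 0.0712 without intact basal replicate 3, the seminal vesicle list 0.0643 without castrated basal replicate 1, and the fibroblast list 0.0960, 0.127 and 0.183 without castrated basal replicate 2, intact basal replicate 2 and intact luminal replicate 3. The apoptosis list had 0.0802 without castrated basal replicate 3 and 0.0697 without intact luminal replicate 1. The interaction count was 27 without an intensity trend, and 83, 92 and 65 without castrated luminal replicate 1, 2 and 3 and 104 without intact basal replicate 2.

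**Figure D3:**
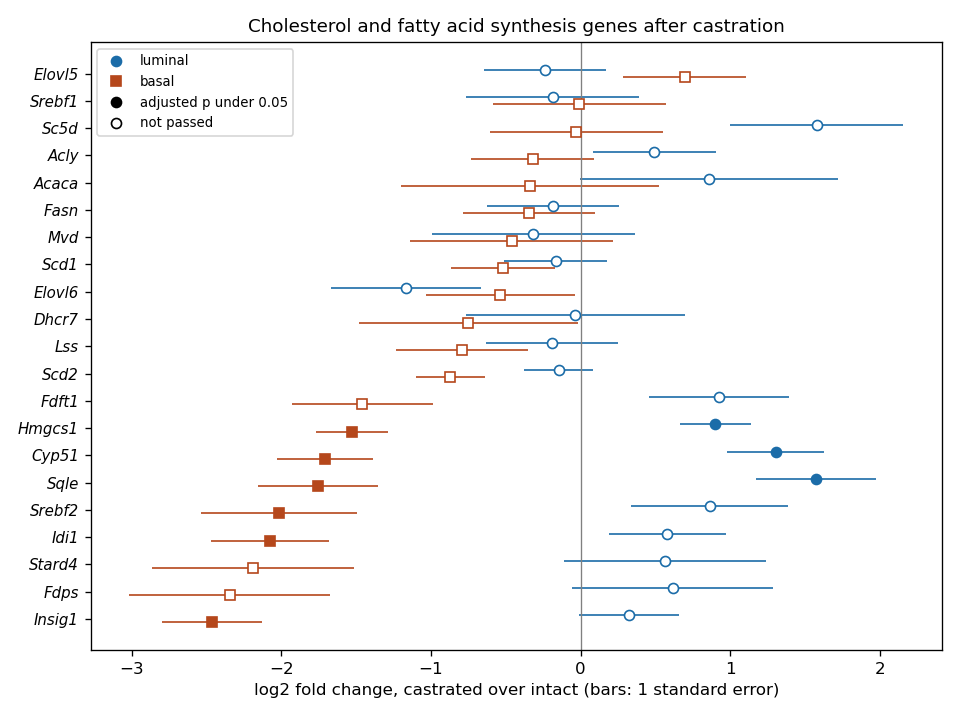
Log2 fold change, castrated over intact, of the 21 measured cholesterol and fatty acid synthesis genes in luminal (circles) and basal (squares) arrays, with bars of 1 standard error, filled where adjusted p was under 0.05. Luminal values of Hmgcs1, Cyp51 and Sqle lie above 0 and their basal values below it.

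The last comparisons set luminal against basal cells. In intact mice 2852 genes differed, 1615 higher and 1237 lower in luminal cells. Those highest in luminal cells were Cyp4a12a (7.31 ± 0.73), Svs6 (6.84 ± 0.89), Nefh (6.62 ± 0.57), Defb42 (6.37 ± 0.87) and Psca (6.23 ± 1.16; 4.65 without intact basal replicate 3). Those highest in basal cells were the zinc-finger repressor Snai2 (-7.38 ± 0.41), Pdk4 (-7.34 ± 0.53), Tenm2 (-7.27 ± 0.57), Aqp3 (-7.24 ± 0.56) and the matrix gene Fmod (-7.15 ± 0.91; -5.89 without intact luminal replicate 3). Of 89 named genes that differed, 8 lay under the 40th percentile on all 3 arrays of the dimmer group, among them Cyp4a12a, Nefh, Tenm2 and Aqp3, whose fold depends on the constant added. The sort markers' cell types showed in the keratins: Krt5 (-7.08 ± 0.68), Krt14 (-7.02 ± 0.48) and Trp63 (-5.76 ± 0.43) were lower in luminal cells, and Krt8 (0.84 ± 0.17), Krt18 (0.55 ± 0.16), Krt4 (3.25 ± 0.67), Pbsn (2.89 ± 0.44) and Mki67 (2.97 ± 0.78) were higher. Of 21 measured basal identity genes, 0 were higher, 18 lower and 3 did not pass (adjusted p = 6.89e-19, or adjusted p = 0.00458 with an estimated correlation); of 16 luminal identity genes, 13 were higher, 1 lower and 2 did not pass, with Krt19 (2.46 ± 0.18) and Prom1 (5.18 ± 0.42). Camera gave an adjusted p of 3.22e-09 and adjusted p = 0.0212 with an estimated correlation.

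In intact mice the protein-folding genes of the endoplasmic reticulum were higher in luminal cells (of 25 measured members, 20 were higher, 1 lower and 4 did not pass; adjusted p = 6.44e-14, or adjusted p = 0.0321 with an estimated correlation), for example Creld2 (3.32 ± 0.35) and Pdia6 (2.79 ± 0.34). Seminal vesicle (8 higher and 0 lower of 8, adjusted p = 1.15e-07, or adjusted p = 0.0600 with an estimated correlation), androgen-dependent (9 higher and 3 lower of 21, adjusted p = 0.0199, or adjusted p = 0.0894 with an estimated correlation) and proximal luminal lists (7 higher and 1 lower of 13, adjusted p = 7.00e-04, or adjusted p = 0.106 with an estimated correlation) were higher as well, Clu leading the last (3.35 ± 0.23). Notch pathway genes were lower in luminal cells, 0 of 15 measured members being higher, 7 lower and 8 not passing (adjusted p = 2.65e-05, or adjusted p = 0.0222 with an estimated correlation), led by the ligands Jag2 (-4.41 ± 0.47), Dll1 (-5.61 ± 0.63) and Jag1 (-3.14 ± 0.41). TGF-beta and BMP (0 higher and 6 lower of 19, adjusted p = 4.40e-04, or adjusted p = 0.0364 with an estimated correlation), stem or progenitor (1 higher and 8 lower of 18, adjusted p = 1.28e-04, or adjusted p = 0.0329 with an estimated correlation), inflammatory (0 higher and 6 lower of 21, adjusted p = 0.00247, or adjusted p = 0.0478 with an estimated correlation) and immediate early genes (0 higher and 7 lower of 18, adjusted p = 4.40e-04, or adjusted p = 0.338 with an estimated correlation) were lower too, with Tgfbr3 (-1.95 ± 0.30), Runx1 (-2.17 ± 0.29), Icam1 (-2.83 ± 0.26) and Ier3 (-1.57 ± 0.16). Fibroblast (0 higher and 3 lower of 12, adjusted p = 0.00341, or adjusted p = 0.122 with an estimated correlation) and smooth muscle markers (0 higher and 1 lower of 8, adjusted p = 0.0326, or adjusted p = 0.338 with an estimated correlation) were lower, with Dcn (-2.94 ± 0.25) and Smtn (-4.36 ± 0.48); the smooth muscle list had adjusted p-values of 0.0707, 0.104 and 0.0932 without intact basal replicate 1 and intact luminal replicate 1 and 2.

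After castration 2701 genes differed, 1643 higher and 1058 lower in luminal cells. The highest in luminal cells were Rnase1 (7.58 ± 0.61), Anxa13 (7.51 ± 0.60), Pnliprp1 (6.94 ± 0.55), Svs4 (6.65 ± 0.64) and Nlrp10 (6.64 ± 0.52); the lowest were Krt5 (-9.16 ± 0.68), Trp63 (-7.95 ± 0.43), Snai2 (-7.93 ± 0.41), Krt14 (-7.90 ± 0.48) and Pdpn (-7.90 ± 0.40). Of 99 named genes that differed, 8 were likewise dim, among them Anxa13, Svs4 and Nlrp10. Pbsn (6.45 ± 0.44), Krt8 (0.62 ± 0.17) and Psca (3.49 ± 1.16, losing its call under 7 of the 12 leave-outs) were higher in luminal cells. Krt4 (0.97 ± 0.67, adjusted p = 0.353), Mki67 (1.79 ± 0.78, adjusted p = 0.126) and Krt18 (-0.20 ± 0.16, adjusted p = 0.416, turning to 0.54 and passing with quantile normalization) did not pass. Basal identity genes were lower, 0 of 21 measured members being higher, 19 lower and 2 not passing (adjusted p = 1.43e-20, or adjusted p = 0.00458 with an estimated correlation), and luminal identity genes higher, 9 of 16 measured members being higher, 1 lower and 6 not passing. The list test gave adjusted p = 2.59e-06, and adjusted p = 0.0310 with an estimated correlation.

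Cholesterol and fatty acid genes were higher in luminal than in basal cells after castration (of 21 measured members, 11 were higher, 0 lower and 10 did not pass; adjusted p = 5.68e-06, or adjusted p = 0.0942 with an estimated correlation), as Scd2 (1.83 ± 0.23) and Cyp51 (1.94 ± 0.32) show, whereas in intact mice the list did not pass (of 21 measured members, 4 were higher, 4 lower and 13 did not pass). The list had an adjusted p of 0.629 and adjusted p = 0.816 with an estimated correlation. Interferon genes were higher in castrated luminal cells (5 higher and 0 lower of 17, adjusted p = 0.00431, or adjusted p = 0.0600 with an estimated correlation), with Xaf1 (3.34 ± 0.71) and Rsad2 (4.27 ± 0.93). Endoplasmic reticulum (14 higher and 2 lower of 25, adjusted p = 5.56e-05, or adjusted p = 0.158 with an estimated correlation) and seminal vesicle genes (4 higher and 0 lower of 8, adjusted p = 0.0129, or adjusted p = 0.295 with an estimated correlation) passed upward, with Dnajc3 (1.85 ± 0.23) and Svs2 (6.18 ± 0.57). Notch (1 higher and 4 lower of 15, adjusted p = 0.00651, or adjusted p = 0.0600 with an estimated correlation), TGF-beta and BMP (1 higher and 5 lower of 19, adjusted p = 0.0199, or adjusted p = 0.106 with an estimated correlation), stem or progenitor (2 higher and 9 lower of 18, adjusted p = 0.00115, or adjusted p = 0.0580 with an estimated correlation) and immediate early genes (0 higher and 9 lower of 18, adjusted p = 3.25e-07, or adjusted p = 0.184 with an estimated correlation) were lower, as were Jag2 (-5.07 ± 0.47), Bmp4 (-4.98 ± 0.59), Id3 (-3.41 ± 0.25) and Socs3 (-2.96 ± 0.37). Fibroblast (0 higher and 4 lower of 12, adjusted p = 1.03e-04, or adjusted p = 0.0600 with an estimated correlation), smooth muscle (0 higher and 3 lower of 8, adjusted p = 0.00241, or adjusted p = 0.184 with an estimated correlation) and leukocyte markers (0 higher and 3 lower of 14, adjusted p = 0.0128, or adjusted p = 0.0924 with an estimated correlation) were lower in luminal arrays, with Dcn (-5.77 ± 0.25), Smtn (-6.08 ± 0.48) and Lyz2 (-2.53 ± 0.59). Without castrated luminal replicate 1, 2 and 3 the count was 1720, 1755 and 1788. Testing every probe set singly gave 5146 in intact and 4683 in castrated mice. Over all comparisons the cell cycle, polyamine, oxidative phosphorylation, Wnt, steroid receptor and enzyme, and reference gene lists did not pass, with lowest adjusted p-values of 0.141, 0.328, 0.187, 0.103, 0.143 and 0.147.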

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

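For the secretory and cholesterol patterns, both tests of carried luminal RNA were chosen after the result was seen. So were the tests of scaling for the secretory, cholesterol and fibroblast patterns. The second fibroblast list was chosen after the fibroblast fall was seen, but before its own values were, except those of C1s1. The castration effect differed between luminal and basal cells for 168 genes. Only 1 of 100 assignments of the residuals of an additive model, the real one, gave as many, the highest other giving 2. The shuffle treats all arrays as alike in spread. Castrated luminal arrays were not, with a median standard deviation of 0.32 log2 units against 0.58 to 0.61 in the other groups. Chance was therefore argued against for this count, but not excluded. Interaction values were 6.32 for Tnfaip2, 5.94 for Rgs4, 5.41 for Mtmr11, 4.998 for Htra1 and 4.94 for Casp12. They were -6.87 for Svs6, -5.52 for Svs3a, -5.49 for Nefh, -5.40 for C1s1 and -5.26 for Defb42. For these 5 negative genes the intact basal signal was too low for a basal fall as large as the luminal one to be measured, which limits the seminal vesicle list as well. With the preset correlation 8 lists differed, with median interactions of -1.12 (proximal luminal), 0.93 (interferon), 1.03 (inflammatory), -0.39 (endoplasmic reticulum), 1.197 (cholesterol), 0.76 (apoptosis), -0.62 (fibroblast) and -2.53 (seminal vesicle). With an estimated correlation the inflammatory list alone held (adjusted p = 0.0222); in the same order the other 7 had adjusted p-values of 0.160, 0.0600, 0.106, 0.0600, 0.106, 0.238 and 0.274. Outside the named genes, 226 of 6256 probe sets without a single gene symbol changed in castrated luminal arrays.

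For the 2-group counts, 3 arrays against 3 make 10 splits, too few for a share under 0.05. Fits over the 2 groups gave 1215 genes for the real luminal split and 0 at most for another, 120 and 1 for basal, 2082 and 0 for cell types in intact mice, and 3322 and 0 in castrated mice. In each case 1 of the 10 splits, the real one, gave as many.

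Secretory genes were measured in intact basal arrays and fell there after castration. If luminal RNA were carried evenly into the basal sort, every abundant luminal gene would show at least that share. The 20 abundant luminal genes with the lowest share had a median basal signal of 2.94% of the luminal one (1.21% to 5.97%), against 9.49% for the 6 secreted products that fell (5.05% to 25.5%), or 10.996% with the transcription factor Zbtb16 of the same list counted in. Both sets were picked on the intact basal arrays, the 20 for a low signal and the 6 for a fall from it. Such picking can widen the gap, so the gap alone does not decide against even carryover. Median centring, which shifts all genes of an array alike, left the median change of these secreted products at -6.37, or -6.02 with Zbtb16. An even shift of that kind does not account for falls of this size, which says nothing on other forms of scaling. Msmb lay within the low-share range, and the highest luminal signals may be compressed. Even carryover and expression by basal cells themselves stay open, as does, untested, carryover from luminal cells rich in secretory RNA. For Svs2, Svs4 and Svs5, RNA from seminal vesicle was not tested either.

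As lists with the preset correlation, cholesterol and fatty acid genes passed downward in basal and upward in luminal cells, but with an estimated correlation adjusted p was 0.0816, 0.384 and, for the interaction, 0.0600; by sign alone 12 of 21 members went up in luminal and down in basal arrays, 3 of them (Hmgcs1, Sqle and Cyp51) passing in both. Under quantile normalization and median centring the median interaction was 1.10 and 1.23, so scaling did not account for the difference between cell types, although the luminal call alone was lost with quantile normalization (adjusted p = 0.123). Without any 1 array it was 0.72 (intact luminal replicate 3 left out) to 2.07 (intact luminal replicate 1 left out). Luminal RNA carried evenly into the basal sort was taken at 2.94% of luminal signal, a share from genes picked as low on the same arrays. It would make up a median of 2.67% of the intact basal signal of the 21 members (upper quartile 6.30%). Their median loss after castration was 46.1% (lower quartile 21.7%). A larger even share and uneven carryover stay open. A cell-type difference in sterol synthesis after castration may therefore be real, as a hypothesis found and tested on these arrays, and it rests mainly on the basal fall, since the luminal call was also lost without intact luminal replicate 3 (0.300).

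Of 12 fibroblast markers 8 fell in luminal and 6 in basal sorts, which the lineage-negative, EpCAM-positive gate should have freed of fibroblasts. A second list, written before its values were seen except for C1s1, had median changes of -1.86 in luminal arrays (92% of 25 members negative) and -1.66 in basal arrays (96%), values that less fibroblast RNA in the castrated sorts may account for; without C1s1 the medians were -1.82 and -1.68. Median centring, which shifts all genes of an array alike, left the smaller median fall at -1.86 and the larger at -2.65. An even shift of that kind does not account for the falls, which says nothing on other forms of scaling. Of 12 markers, 5 had a signal over 1000 in intact basal, 4 in castrated basal, 5 in intact luminal and 1 in castrated luminal arrays, and 0 genes of the second list stood in a fixed list. In basal arrays Dcn, at 21080 and 22092, and Fbln1, at 453 and 669, were not lower and would need another source there, and lower expression by epithelial cells was not tested and stays open.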

How the results depend on the processing

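Leaving out the 2 arrays of lowest weight was chosen after the result was seen; every other alternative was planned. The cause of each shift below was not tested. Without an intensity trend 555 genes changed in castrated luminal cells, 155 in basal cells, 27 in the interaction and 41 in both castration comparisons. Testing probe sets singly gave 1562, 618, 5146 and 4683 in the luminal, basal, intact and castrated comparisons, with more features tested. Array weights gave 1945 in luminal and 202 in basal cells. A fit over the 2 basal groups, which takes no spread from luminal arrays, gave 120, and a fit over the 2 luminal groups gave 1215. Median centring, which moved the median of all genes from -0.09 to 0.29 in luminal and from -0.11 to 0.23 in basal cells, gave 626 in basal cells and 177 shared genes. It raised the share of higher genes from 49.4% to 80.2% of 1273 in luminal and from 42.7% to 81.6% in basal cells, so the balance of rises and falls depends on scaling. With an estimated correlation 18 of 54 list calls held. Leaving out 1 array gave 401 to 984 genes in luminal and 175 to 623 in basal cells, 2160 to 3138 and 1720 to 3109 between cell types in intact and castrated mice, 65 to 163 in the interaction, 44 to 104 shared genes, a correlation of both castration effects of 0.256 to 0.292, and 51 to 56 list calls. With the replicate number as a block the counts were 805, 318, 2778, 2687 and 129, with 95 shared genes and 56 list calls. Without both arrays of lowest weight they were 707, 491, 3084, 2781 and 167, with 111 shared genes and 51 list calls. Quantile normalization turned the direction of Cd24a (to 0.0228), Rpl13a (0.0540), Actb (0.20) and Krt18 (0.41) in castrated luminal cells. It also turned Sprr1a (0.0358), Atp5a1 (0.14) and Krt18 (0.54) between castrated cell types. Under it 422 of 458 results (named genes, passing lists and the correlation of both castration effects) were counted as unchanged. For genes this meant the same side of the threshold. A change of direction was counted only where the gene passed in either fit. Leaving out 1 array at a time, 26 of 73 named calls in luminal and 18 of 49 in basal cells were lost at least 1 time. Between cell types 16 of 89 in intact and 20 of 99 in castrated mice were lost, and in the interaction 13 of 34. Signal near background limits folds: of the named genes past the threshold, 12 of 73 (luminal), 4 of 49 (basal), 8 of 89 and 8 of 99 (between cell types in intact and castrated mice) lay under the 40th percentile on all 3 arrays of their dimmer group, and 8 of 34 interaction genes did so in at least 1 group.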

Other observations

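The test of squamous genes was chosen after rises of 2 members had been seen; the hypoxia test was chosen before its values were seen. Several genes outside the lists that passed changed with castration. The Wnt inhibitor Wif1 fell in luminal (-2.46 ± 0.58) and basal arrays (-2.71 ± 0.58), and the transcription factors Lef1 (-2.78 ± 0.61, luminal) and Tcf7l2 (-1.06 ± 0.27, basal) fell as well. The R-spondin receptor Lgr4 rose in luminal arrays (1.71 ± 0.35), with a positive interaction (2.27 ± 0.49, adjusted p = 0.0323; 0.0539 with the replicate number as a block). Tgfb3 fell in basal arrays (-3.19 ± 0.76).

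Of 26 cell cycle genes in luminal arrays, 2 rose, 2 fell and 22 did not pass. Their median change was -0.53, with an adjusted p of 0.141 by camera and, downward, 0.00285 by the self-contained test. Rrm2, a subunit of ribonucleotide reductase, fell in luminal (-1.996 ± 0.35) and basal arrays (-1.76 ± 0.35), and E2f1 fell in luminal arrays (-2.52 ± 0.58), while the helicase subunit Mcm6 (1.75 ± 0.35) and the sliding clamp Pcna (0.79 ± 0.22, adjusted p = 0.0425; 0.0519 with the block) rose there. Odc1, the first enzyme of polyamine synthesis, fell in luminal arrays (-0.90 ± 0.15). The heme synthesis gene Alas2 rose (3.57 ± 0.58) where the globin gene Hbb-b2 fell (-3.76 ± 0.57). In basal arrays Gpx1 fell (-1.01 ± 0.18).

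Rises of Krt6a (3.69 without intact luminal replicate 3, its dimmest array) and Ivl prompted the hypothesis of a squamous and wound keratinocyte programme in castrated luminal cells. A list of 15 measured genes had a median change of 0.84 (camera, adjusted p = 0.00328 over the added lists, or 0.0373 with an estimated correlation), and Krt6a, Ivl, Krt16 (2.34 ± 0.60) and Dsc2 (1.52 ± 0.44) rose. Without Krt6a and Ivl the median of the other 13 was 0.20 with an unadjusted p of 0.0280, so the list as a whole leaned on the members already seen and the hypothesis stays open. In basal arrays the list had an adjusted p of 0.0440, or 0.0897 with an estimated correlation. A hypoxia and glycolysis programme, prompted by Ndrg1, stays open: its 20 genes had a median change of -0.0888 (adjusted p = 0.893), but 8 were positive and 12 negative. Pfkfb3, which makes an activator of glycolysis, fell (-2.97 ± 0.27), while Aldoc (2.53), Ankrd37 (2.09), Egln3 (1.67), Pdk1 (1.13) and Car9 (1.05) were positive without passing. By the rule written before these values were seen, a list with so low a median that did not pass counted against the programme. The condition that the spread of the members be counted, which left the programme open, was set after the median was seen.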
